A study of Mus musculus with 8 samples.

How the data were processed

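Total RNA of 8 samples, 2 from each of 4 groups, was labelled with the dye Cy3 and hybridised to 1-colour Agilent mouse expression arrays that share 1 slide and 1 scan date, per the file headers. Per the labels' protocols, 200 ng of RNA entered the labelling, and RNA of the cells and of the ventricle was extracted with different reagents. The deposited scanner files hold spot intensity values from Agilent Feature Extraction 10.7, per the submitters' processing notes. Its processed signal is an intensity after background subtraction and spatial detrending within the array, per the file headers, with no normalization between arrays. The authors' values are log2 units, not centred per gene, with column medians from 6.087 to 6.094. Within each array its values ranked as the median spot signal minus the local background (rank correlation 1), and its columns are close to each other in distribution, though not identical, with ranges of 18.3026 log2 units in 1 array and 18.378 in the other 7. The tool behind it is not given in the sources used here.

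Each array holds 62976 spots, of which 3671 are controls and were left out, with 167 to 248 outlier spots per array. No spot was saturated. Repeated spots of 1 probe were averaged, giving 55681 probes and 34741 gene names. Probe accessions were matched to a RefSeq gene table for 27235 probes, which updated the symbol of 3403, and other names are those of the array design. Of the 34741 names, 11199 have more than 1 probe, and the probe with the highest mean over all 8 arrays was used. Among the 4677 genes passing in CD45-negative against CD45-positive cells, 1283 had several probes tested, with some probe not passing for 665 and passing in the opposite direction for 30. Coordinates are those of the files in build mm9.

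Values are log2 of the processed signal minus each array's 75th percentile, so a log2 difference compares shares of the signal and not amounts per cell. All 8 arrays were fitted with limma 3.58.1 (lmFit and eBayes, R 4.3.3) with 1 mean per group and a pooled spread, which left 4 residual and 5.876 total degrees of freedom. Every SE given with a log2 difference rests on this pooled spread, not on the spread of the 2 groups compared alone. A gene entered a comparison when it was well above background on both arrays of at least 1 of the groups compared. It passed at a Benjamini-Hochberg adjusted p under 0.05 within the comparison and an absolute log2 difference of at least 1, and every p is two-sided. An exact permutation of 2 arrays against 2 cannot go below p = 0.333, so none is given. Where 1 group was not well above background on any of its arrays the fold is a lower bound. It sets the bright group's mean against the dim group's mean of, per array, the higher of the probe's own signal and the lowest signal well above background.

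Gene lists were fixed before the data were examined, as were the comparisons, thresholds and all processing alternatives except 1 named in the closing section. There were 31 lists of cell type markers and pathways, 29 of them tested as sets where at least 5 members were tested, with limma's camera at a preset correlation of 0.01, then with an estimated correlation and with fry, a self-contained test. Benjamini-Hochberg adjustment covered the lists of a comparison. Camera passed 10, 12, 12, 20, 17 and 19 lists in the comparisons of CD45-negative and passage-8 cells with CD45-positive cells, passage-8 with CD45-negative cells, and the CD45-negative, CD45-positive and passage-8 cells with ventricle. With an estimated correlation 0 passed in each of the 6, and with fry 9, 11, 11, 19, 17 and 19. The median difference of all tested genes was 0.17 in CD45-negative and 0.16 in passage-8 cells against CD45-positive cells, and list medians are given without subtracting it.

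Named genes followed a rule. It took Kit and Ptprc, and among cells the 6 highest and 6 lowest log2 differences of genes that passed and were well above background and unsaturated on all arrays of both groups. It added the 4 highest bounds in each direction, and against ventricle took 4 and 2 in place of 6 and 4. Clone and accession names were skipped, and up to 4 members that passed per direction were open to naming from each list, with the members behind any count of 5 or fewer.

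The fit was tested on simulated data for CD45-negative against CD45-positive cells. Over 21509 genes, 58 of 100 genes changed by 2 log2 units and 95 of 100 changed by 4 passed, with 1 unchanged gene passing. A changed list passed and 0 of 20 unchanged lists did, over 34741 genes. The simulated noise was drawn independently for each gene, with the same spread in every group. It therefore does not test lists of correlated genes or groups that differ in spread. Alternatives covered normalization, background correction (normexp with an offset of 50), the authors' value table, the filter on dim probes, several probes per gene, thresholds, moderation, the arrays in the fit, array weights, the replicate number as a term and each array left out in turn. Tables and plots used the R package data.table (1.17.8), Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.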

Results

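Gene expression was measured in mouse heart cells and heart muscle on 8 one-colour Agilent arrays, 2 for each of 4 groups. The first group held primary cells that carried the receptor tyrosine kinase c-kit but lacked CD45, the phosphatase found on the surface of white blood cells. They were sorted from explant cultures of the left atrial appendage, a pouch of the left atrium, after a strong digestion with 0.25% trypsin, and are called CD45-negative cells here. The second group held primary c-kit-positive cells that also carried CD45, grown from the same tissue after a weak digestion with 0.05% trypsin, called CD45-positive cells. The third group, passage-8 cells, was derived from the CD45-positive cells by growth to passage 8, and the fourth was biopsied wall of the left ventricle, the study's control. The design asks how the 2 primary cell types differ and whether macrophage-like precursors come to resemble the CD45-negative cells in culture. Mice were C57BL/6 animals 8 to 12 weeks old, and the ventricle donors were 12 weeks old.

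The 75th percentile of the signal lay between 426 and 521 in the CD45-negative arrays, 569 and 600.2 in left ventricle, 839 and 897 in CD45-positive cells and 974 and 976 in passage-8 cells. Between 51.5% and 69.9% of spots were well above background. Replicates differed most in CD45-negative cells, with a standard deviation of 0.755 log2 units over 17961 genes, against 0.512 in left ventricle, 0.247 in CD45-positive and 0.206 in passage-8 cells. Array number limits the precision of every value. The labels do not say that the replicates came from separate cultures or animals, so p-values measure only the spread between these samples, which may be technical.

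Ptprc, the gene of CD45, followed the sort gate. Relative to the 75th percentile of each array, its log2 signal was 1.98 ± 0.08 (SD, n = 2) in CD45-positive cells, -4.43 ± 1.54 in CD45-negative cells, -5.37 ± 0.28 in passage-8 cells and -2.61 ± 0.40 in left ventricle, each with n = 2. It was 85.5-fold lower in CD45-negative than in CD45-positive cells (limma adjusted p = 0.00367) and 164-fold lower in passage-8 cells (limma adjusted p = 0.00167), and on replicate 1 of the CD45-negative cells it was not well above background. Kit, the gene of c-kit, had a log2 signal of -3.45 ± 0.17 in CD45-positive cells, -5.62 ± 0.09 in passage-8 cells and -1.98 ± 0.71 in left ventricle (SD, n = 2 each). In CD45-negative cells it was not well above background on replicate 1 and stood at -1.55 on replicate 2. Kit passed the test in none of the 6 comparisons, with limma adjusted p-values from 0.0865 to 0.824. The probes lie on chromosome 1 from 139961083 to 139961142 for Ptprc and on chromosome 5 from 76052394 to 76052453 for Kit, in build mm9.

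**Figure D1:**
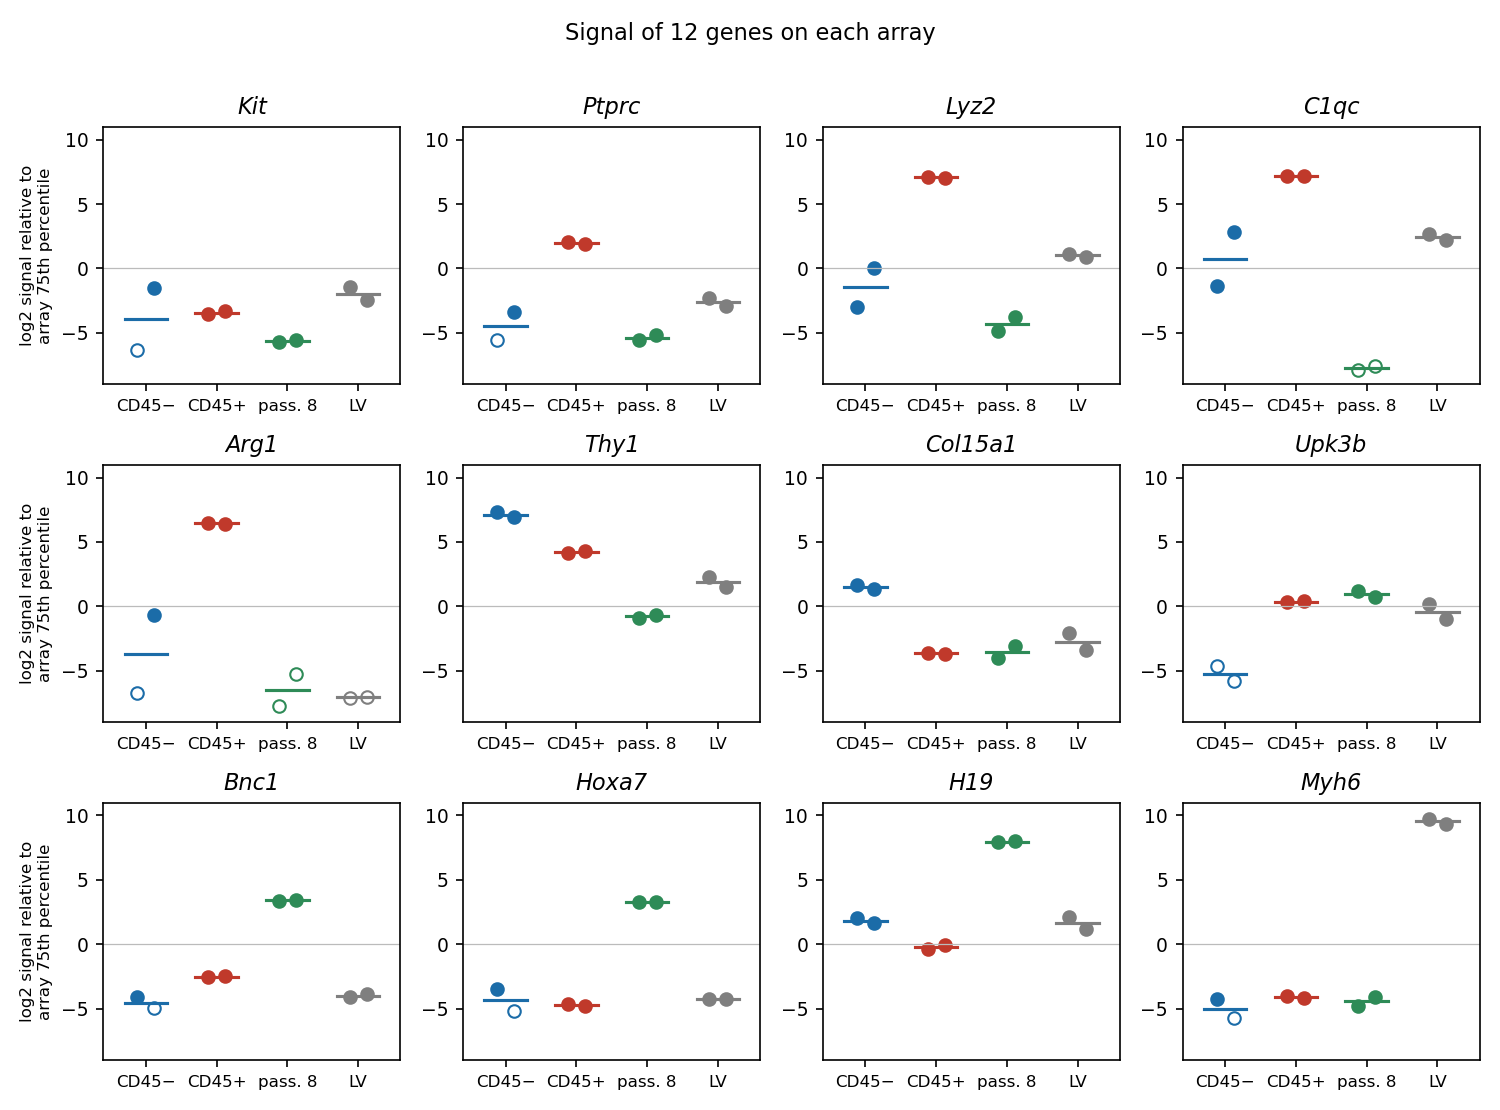
Signal of 12 genes on each of the 8 arrays, as log2 relative to the array's 75th percentile, with 1 point per array, a bar at the mean of each group of 2, and open points for signal not well above background. Ptprc and the macrophage genes Lyz2, C1qc and Arg1 were highest in CD45-positive cells, Thy1 and Col15a1 in CD45-negative cells, Bnc1, Hoxa7 and H19 in passage-8 cells and Myh6 in left ventricle.

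The CD45-negative and CD45-positive primary cells differed in macrophage and connective tissue genes. Lysozyme Lyz2, an antibacterial enzyme of macrophages, was 369.8-fold lower in CD45-negative cells (log2 difference -8.53, SE 0.95, n = 2 per group), and the complement genes C1qa and C1qb, which tissue macrophages make, were 269-fold and 171-fold lower. The growth factor pleiotrophin (Ptn) was 41.1-fold higher (log2 difference 5.36, SE 0.94, n = 2 per group), the basement membrane collagen Col15a1 35.6-fold higher and Ltbp1, which binds latent TGF-beta, 29.0-fold higher. These SEs rest on the spread pooled over all 4 groups, whereas the 2 CD45-negative replicates differed by 3.02 log2 units for Lyz2. Of 21506 genes tested with limma, 2417 were higher and 2260 lower in CD45-negative cells. Without replicate 1 or 2 of the CD45-negative cells the log2 differences ran for Lyz2 from -10.04 to -7.02, C1qa from -9.98 to -6.16, C1qb from -8.96 to -5.88 and Ptn from 3.79 to 6.93, and 47 of 120 genes open to naming here moved by over 1.5 times with 1 array left out.

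Among the genes with the largest falls were also Wfdc17 (246-fold), the C-type lectin receptor Clec4d (187-fold) and the B-cell linker gene Blnk (171-fold). Cd200r4, Fcna, Pld4 and Otulinl were well above background only in CD45-positive cells, which puts them at least 168-fold, 81.2-fold, 81.1-fold and 70.7-fold lower in CD45-negative cells. Tpbg, Syt10 and the actin-severing gene Scin were 32.7-fold, 24.7-fold and 23.1-fold higher. Ankrd7, Ccdc3, Prokr2 and the natriuretic peptide Nppc were well above background only in CD45-negative cells, at least 31.9-fold, 17.8-fold, 16.4-fold and 12.7-fold higher.

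Macrophage and monocyte genes fell as a group in CD45-negative cells, with 25 of 28 tested genes lower and 1 higher (1 higher and 26 lower when adjusted over the list alone) and a median log2 difference of -6.56 (camera adjusted p = 3.09e-11, and adjusted p = 0.587 with an estimated correlation). With 1 array left out this median ran from -8.45 to -4.51. The 1 higher gene was the integrin Itgam (3.12-fold), whose mean over all probes went the other way (log2 difference -1.52). Lysosome and phagocytosis genes fell too, with 21 of 25 lower and 1 higher (1 higher and 21 lower when adjusted over the list alone, camera adjusted p = 2.38e-12, and adjusted p = 0.110 with an estimated correlation). Among them were cathepsin S (Ctss, 168-fold) and the scavenger receptor Cd36 (192-fold, measured on 1 of 2 CD45-negative arrays). The receptor kinase Axl was higher by a log2 difference of 1.85. Of 14 genes of antigen presentation and dendritic cells, 10 were lower and 0 higher (0 higher and 10 lower when adjusted over the list alone, camera adjusted p = 9.07e-06, and adjusted p = 0.442 with an estimated correlation). The invariant chain Cd74 was at least 31.7-fold lower. Of 25 cytokine and chemokine genes 11 were lower, 2 higher and 12 did not pass (2 higher and 11 lower when adjusted over the list alone, camera adjusted p = 0.00173, and adjusted p = 0.491 with an estimated correlation). The chemokines Ccl3 and Ccl4 were lower, by log2 differences of -6.74 and -6.70, each measured on 1 of 2 CD45-negative arrays. Cxcl12, a stromal chemokine, was 5.67-fold higher.

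Fibroblast and mesenchymal stromal genes rose in CD45-negative cells, with 14 of 25 higher and 1 lower (15 higher and 1 lower when adjusted over the list alone) and a median log2 difference of 1.33 (camera adjusted p = 1.74e-05, and adjusted p = 0.110 with an estimated correlation). The fibroblast activation protein Fap was 8.20-fold higher, the surface antigen Thy1 7.66-fold, and the transcription factors Twist2 and Twist1 7.56-fold and 7.05-fold. The adhesion molecule Alcam was 12.1-fold lower. Members of this list measured in both groups had a median signal in CD45-negative cells of 250.8% of that in CD45-positive cells. Extracellular matrix genes rose as well (17 of 35 higher and 1 lower, 22 higher and 1 lower when adjusted over the list alone, camera adjusted p = 6.02e-05, and adjusted p = 0.442 with an estimated correlation). Fbln1 was 8.74-fold higher and Fmod 11.3-fold lower. Regulators of the epithelial-mesenchymal transition included 8 higher and 1 lower genes of 16 (8 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0497, and adjusted p = 0.794 with an estimated correlation). Cdh11 and Snai2 were 7.43-fold and 7.37-fold higher. Epithelial and mesothelial genes fell, with 7 of 11 lower and 0 higher (1 higher and 8 lower when adjusted over the list alone, camera adjusted p = 6.02e-05, and adjusted p = 0.110 with an estimated correlation). The mesothelial genes Upk3b and Upk1b were at least 30.8-fold and 25.7-fold lower.

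The fat cell list had 3 of 5 genes lower (0 higher and 4 lower when adjusted over the list alone, camera adjusted p = 0.00173, and adjusted p = 0.222 with an estimated correlation). These were Cebpa, Fabp4 and Pparg, all of which macrophages also express. The cell cycle list had 4 of 30 genes higher and 1 lower (4 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0497, and adjusted p = 0.892 with an estimated correlation). The higher ones were Cdc20, Foxm1, Mcm7 and Ccne1, and the lower one was Pcna. None of 13 tested pluripotency genes passed the test in either direction (camera adjusted p = 0.859). At an unadjusted p under 0.05 the list held 1 higher gene (Dnmt3l) and 1 lower gene (Tfcp2l1). Digestion strength and sort gate changed together between these groups, so their effects cannot be separated. Without replicate 1 or 2 of the CD45-positive cells the number of genes passing fell from 4677 to 1120 or 802. This number rose without replicate 2 of the CD45-negative cells, which took the replicate pair that differed most out of the pooled spread. The cell cycle list no longer passed without replicate 1 of the CD45-negative cells (adjusted p = 0.540) or of the CD45-positive cells (0.0843). The regulators of the epithelial-mesenchymal transition no longer passed without replicate 1 (adjusted p = 0.222) or 2 (0.0661) of the CD45-negative cells or replicate 1 of the CD45-positive cells (0.0746).

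Most macrophage transcripts were far lower in passage-8 cells than in the CD45-positive cells they were grown from per the labels, and Hox genes were higher. The chemokine Ccl6 was 3102-fold lower (log2 difference -11.60, SE 1.13, n = 2 per group), Lyz2 2635-fold lower and the platelet factor Pf4 1180.0-fold lower. The imprinted genes H19 and Plagl1 were 290.3-fold and 267-fold higher, and Igf2, the imprinted growth factor next to H19, at least 101-fold higher. The homeobox gene Hoxa7 was 254-fold higher (log2 difference 7.99, SE 0.54, n = 2 per group) and the alarmin cytokine Il33 173-fold higher. Of 23422 genes tested with limma, 2953 were higher and 2556 lower in passage-8 cells. With 1 array left out 16 of 139 genes open to naming moved by over 1.5 times, among them Arg1 from -14.18 to -11.68, Ms4a7 from -15.03 to -13.22, Wfdc17 from -14.58 to -12.97 and Fbxo15 from 2.25 to 3.81 in log2 difference.

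Further large falls were those of Clec4n (1155-fold), Mpeg1 (1150.0-fold), which encodes a pore-forming protein of macrophages, and Alox5ap (1069-fold), needed for leukotriene synthesis. Lilrb4a, Wfdc17, Ms4a7 and C1qc were not well above background on either passage-8 array, and were at least 10228-fold, 10083-fold, 8714-fold and 7698-fold lower. Ptn was 185-fold and Chrdl2, a binder of bone morphogenetic proteins, 128-fold higher. Dmrt2, Ppp2r2b and Hoxd8 were well above background only in passage-8 cells, at least 163-fold, 130.4-fold and 111-fold higher.

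Of 28 tested macrophage and monocyte genes, 26 fell and 0 rose in passage-8 cells (0 higher and 27 lower when adjusted over the list alone). The median log2 difference was -9.23, or -8.90 with genes at their bound (camera adjusted p = 3.94e-15, and adjusted p = 0.381 with an estimated correlation). Lysosome genes fell (22 of 25 lower and 1 higher, 1 higher and 23 lower when adjusted over the list alone, camera adjusted p = 6.93e-14, and adjusted p = 0.127 with an estimated correlation). So did genes of antigen presentation (12 of 14 lower and 1 higher, 1 higher and 12 lower when adjusted over the list alone, camera adjusted p = 1.17e-07, and adjusted p = 0.200 with an estimated correlation). Cytokine and chemokine genes fell in 18 of 25 cases and rose in 1 (1 higher and 18 lower when adjusted over the list alone, camera adjusted p = 3.19e-08, and adjusted p = 0.199 with an estimated correlation). The riser was again Cxcl12 (17.8-fold). Of 8 neutrophil genes 5 fell and 0 rose (0 higher and 7 lower when adjusted over the list alone, camera adjusted p = 0.000886, and adjusted p = 0.199 with an estimated correlation). The matrix protease Mmp9 was at least 58.2-fold lower. Of 9 genes of alternative macrophage activation 5 fell and 2 rose (2 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.0173, and adjusted p = 0.199 with an estimated correlation). Arginase Arg1 was at least 4069.6-fold lower.

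Hox genes rose in passage-8 cells, with 17 of 20 tested members of the list higher and 0 lower (18 higher and 0 lower when adjusted over the list alone). The median log2 difference was 4.07, or 3.39 with genes at their bound (camera adjusted p = 2.64e-09, and adjusted p = 0.127 with an estimated correlation). Hoxd4 and Hoxa5 were at least 69.6-fold and 40.8-fold higher. Epithelial and mesothelial genes rose, 7 of 12 higher against 1 lower (7 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0115, and adjusted p = 0.199 with an estimated correlation). The zinc finger gene Bnc1 was 61.1-fold and keratin 7 (Krt7) 20.2-fold higher and keratin 5 (Krt5) 2.21-fold lower. Cell cycle genes rose in 9 of 30 cases and fell in 0 (9 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.00204, and adjusted p = 0.737 with an estimated correlation). Bub1b was 4.21-fold higher. Senescence and p53 genes fell in 7 of 15 cases and rose in 1 (1 higher and 8 lower when adjusted over the list alone, camera adjusted p = 0.00315, and adjusted p = 0.199 with an estimated correlation). Among them were the cell cycle inhibitors Cdkn2b (10.1-fold) and Cdkn2a (9.32-fold).

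Of 18 endothelial genes 9 fell and 1 rose (2 higher and 9 lower when adjusted over the list alone, camera adjusted p = 0.0120, and adjusted p = 0.524 with an estimated correlation). Their median was -2.12, or -1.01 with genes at their bound, and its direction turned, to 0.14, on genes well above background on all 8 arrays. Von Willebrand factor (Vwf) was 82.3-fold lower. Of 7 Schwann cell and neural crest genes 3 fell and 0 rose (0 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.0107, and adjusted p = 0.199 with an estimated correlation). The lower genes were Ngfr, Kcna1 and Nes. Fibroblast genes moved both ways, 5 higher and 7 lower of 25 (6 higher and 7 lower when adjusted over the list alone, camera adjusted p = 0.415). Lumican (Lum) was 7.12-fold higher and Thy1 31.4-fold lower. Among 14 pluripotency genes Fbxo15 was at least 2.90-fold higher and Dnmt3l 4.14-fold lower (1 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.409). Without replicate 1 or 2 of the CD45-positive cells the number of genes passing fell from 5509 to 2410 or 2182, and without replicate 2 of the passage-8 cells to 2889. Without replicate 1 of the passage-8 cells the neutrophil list (adjusted p = 0.0524) and the alternative activation list (adjusted p = 0.0890) no longer passed.

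Passage-8 cells also differed from the CD45-negative cells, in the comparison that asks how near the cultured derivatives came to the primary CD45-negative type. Plagl1 was 141-fold higher (log2 difference 7.14, SE 0.30, n = 2 per group), the cell surface proteoglycan Gpc3 84.6-fold and the mesothelial gene Lrrn4 82.4-fold higher in passage-8 cells. Thy1 was 241-fold lower (log2 difference -7.91, SE 0.31, n = 2 per group) and Aldh1a2, which makes retinoic acid, 307-fold lower. Of 22757 genes tested with limma, 1585 were higher and 1588 lower in passage-8 cells. The balance depended on background correction, since 31.4% of the genes passing were higher under normexp, against 49.95%. With 1 array left out 34 of 111 genes open to naming moved by over 1.5 times, among them Gpc3 from 4.89 to 7.92, Aldh1a2 from -9.31 to -7.21, Hoxa7 from 6.75 to 8.46, Gpm6a from 6.24 to 7.79 and Cxcl14 from -8.92 to -6.36 in log2 difference.

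H19, Cyp2s1 and the matrix proteoglycan fibromodulin (Fmod) were 71.8-fold, 70.3-fold and 69.6-fold higher in passage-8 cells. Dmrt2, Ppp2r2b, the decarboxylase Ddc and Igf2 were well above background only there, at least 96.1-fold, 76.9-fold, 70.4-fold and 59.4-fold higher. Smim41, Ndufa4l2 and the chemokine Cxcl14 were 319-fold, 203-fold and 199-fold lower. Cd200, Scin, Esm1 and Cav3 were well above background only in CD45-negative cells, at least 348-fold, 336-fold, 253-fold and 168-fold lower.

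Hox genes were higher in passage-8 than in CD45-negative cells in 16 of 20 cases and lower in 0 (17 higher and 1 lower when adjusted over the list alone). Their median log2 difference was 3.85, or 2.52 with genes at their bound (camera adjusted p = 6.00e-10, and adjusted p = 0.0776 with an estimated correlation). Hoxa7 was 195-fold and Hoxb7 68.9-fold higher, each measured on 1 of 2 CD45-negative arrays. Epithelial and mesothelial genes were higher in 9 of 12 cases and lower in 0 (9 higher and 0 lower when adjusted over the list alone). The median of this list was 5.04, or 4.54 with genes at their bound (camera adjusted p = 1.60e-06, and adjusted p = 0.0776 with an estimated correlation). Bnc1 was 247-fold and the membrane glycoprotein Gpm6a 129-fold higher, each again measured on 1 of 2 CD45-negative arrays. Fibroblast genes fell in 11 of 25 cases and rose in 0 (0 higher and 11 lower when adjusted over the list alone, camera adjusted p = 1.79e-06, and adjusted p = 0.0776 with an estimated correlation). Twist2 was 57.3-fold lower.

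Macrophage and monocyte genes were lower still in passage-8 cells, 7 of 23 against 0 higher (0 higher and 8 lower when adjusted over the list alone, camera adjusted p = 0.000503, and adjusted p = 0.561 with an estimated correlation). This rested on replicate 2 of the CD45-negative cells, without which the median went from -2.62 to -1.05 and the list no longer passed (adjusted p = 0.133). C1qc was at least 88.6-fold lower, and with 1 array left out the log2 difference ran for C1qc from -10.56 to -6.37. Senescence genes fell in 4 of 15 cases and rose in 0 (0 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.00681, and adjusted p = 0.284 with an estimated correlation). Among them were Cdkn2a (26.6-fold) and Cdkn2b (26.0-fold). Regulators of the epithelial-mesenchymal transition were lower in 6 and higher in 1 of 16 cases (1 higher and 10 lower when adjusted over the list alone, camera adjusted p = 0.000483, and adjusted p = 0.401 with an estimated correlation). Foxc2 was 19.5-fold lower. Cytokine genes fell in 8 of 17 cases and rose in 2 (2 higher and 10 lower when adjusted over the list alone, camera adjusted p = 0.00643, and adjusted p = 0.183 with an estimated correlation). Cardiac transcription factors fell in 4 of 9 and rose in 0 (2 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.0348, and adjusted p = 0.340 with an estimated correlation). These were Tcf21, Tbx18, Tbx20 and Gata4. None of 30 cell cycle genes passed the test (camera adjusted p = 0.108). At an unadjusted p under 0.05 this list held 4 higher genes and 1 lower gene.

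The test also passed lysosome genes (7 of 23 lower and 0 higher, 0 higher and 8 lower when adjusted over the list alone, camera adjusted p = 0.0248, and adjusted p = 0.401 with an estimated correlation). Antigen presentation did so too (4 of 12 lower and 1 higher, 2 higher and 7 lower when adjusted over the list alone, camera adjusted p = 0.0348, and adjusted p = 0.538 with an estimated correlation). Of 6 neutrophil genes 3 were lower and 0 higher (0 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.0348, and adjusted p = 0.303 with an estimated correlation). The lower ones were Ly6g, Mpo and Camp. Without replicate 1 of the passage-8 cells the direction of this list turned, to a median of 0.15 (adjusted p = 0.600), and it no longer passed without replicate 2 of the CD45-negative cells (0.573) or of the ventricle (0.0501). Of 6 Schwann cell genes Nes and Ngfr were lower (0 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.0411, and adjusted p = 0.401 with an estimated correlation). With only the 4 arrays of these groups in the fit, the genes passing fell from 3173 to 181, and with array weights to 2094. Without replicate 1 or 2 of the passage-8 cells they numbered 900 or 851, and without either CD45-positive replicate 1568. They numbered 5175 without replicate 1 of the CD45-negative cells and 4117 without replicate 2 of these cells, where 7 lists passed in place of 12. Of the 12 lists, 5 passed whichever array was left out, and those that did not were the macrophage, antigen presentation, neutrophil, cardiac transcription factor, Schwann cell, senescence and lysosome lists.

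**Figure D2:**
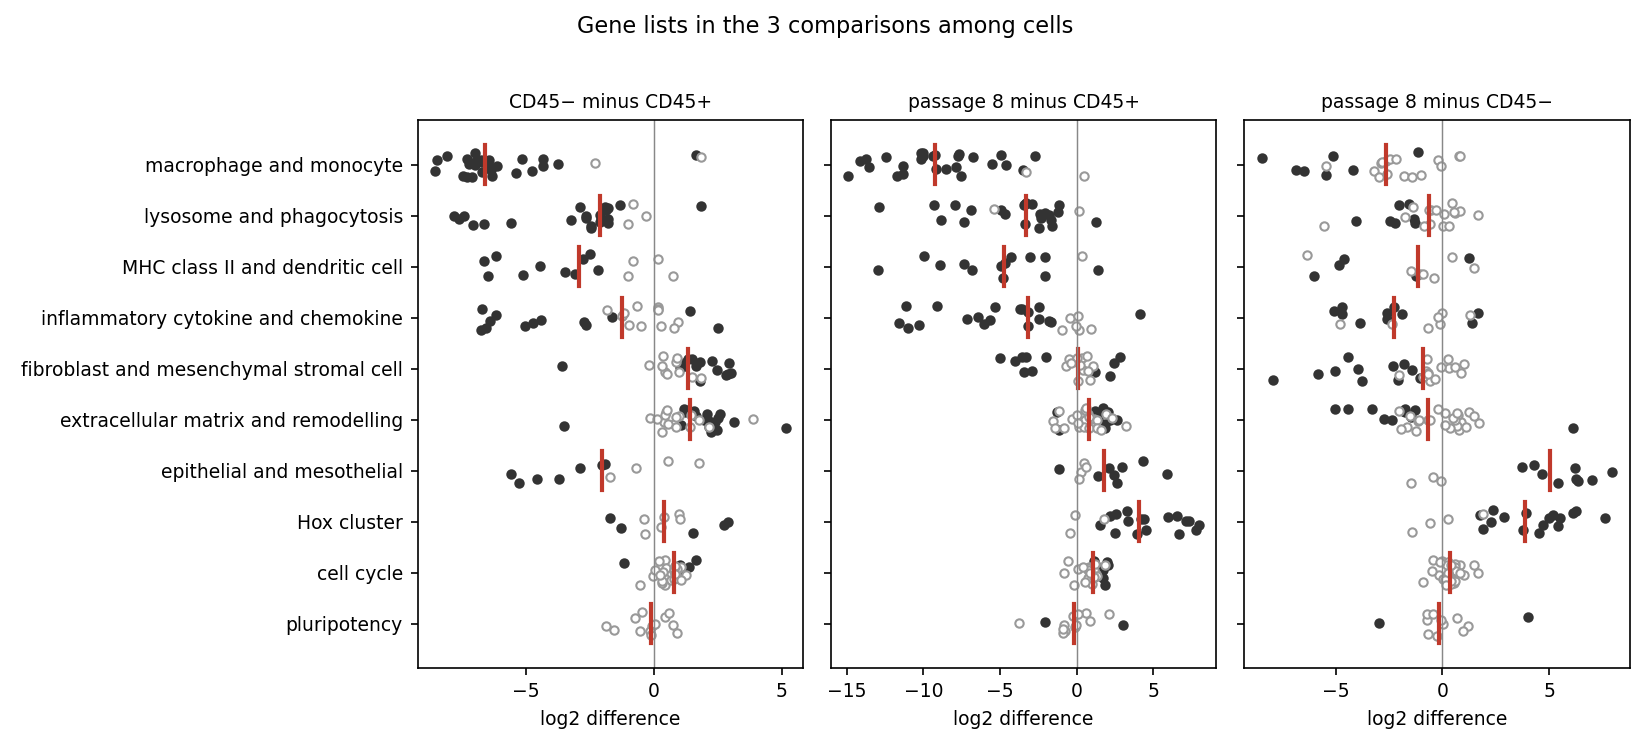
Log2 differences of the tested members of 10 gene lists in the 3 comparisons among cells, with 1 point per gene, filled where the gene passed the limma test, and a vertical bar at the median of each list. Macrophage genes lie far below 0 in both comparisons with CD45-positive cells, at medians of -6.56 and -9.23, and Hox genes lie above 0 in both comparisons of passage-8 cells, at medians of 4.07 and 3.85.

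The differences of CD45-negative and of passage-8 cells from CD45-positive cells were compared gene by gene. Of 21421 genes tested in both, 1111 were higher in both and 1476 lower in both, 2587 in all, and 150 passed in opposite directions. Independent lists of these sizes would share 262 and 270 genes. Simulated unchanged groups set against the same simulated CD45-positive arrays shared 0 in 20 simulations. That 0 is no baseline for the shared count, since with no group changed almost no gene could pass in either comparison. The covariance of the log2 differences was 1.67 against a simulated 0.084, and their correlation across genes 0.733, although genes are not independent replicates. The simulated correlation of 0.501 is no baseline either, since equal noise and the shared arrays fix it whatever the data show. Less the simulated part, which stands for noise of the shared arrays at the pooled spread, the covariance was 1.59. The 2 shared arrays cannot be split into separate pairs, so how much the shared controls add to the shared count was not measured. Without replicate 1 or 2 of the CD45-positive cells the shared genes numbered 672 or 503, and without replicate 1 or 2 of the passage-8 cells 1647 or 1602, alternatives that were chosen after seeing the data.

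Against left ventricle, CD45-negative cells had far lower levels of most heart muscle transcripts and were rich in matrix and cytokine genes. Myoglobin (Mb) and the ventricular light chain Myl2 were not well above background on either CD45-negative array, and were at least 20031-fold and 16660.0-fold lower. The protease inhibitor Timp1 was 356-fold higher (log2 difference 8.47, SE 0.40, n = 2 per group), the matrix protease Mmp3 287-fold and Plac8 527-fold higher, and the cytokine Il6 at least 518-fold higher. Of 22265 genes tested with limma, 4520 were higher and 4280 lower in CD45-negative cells. With 1 array left out 55 of 143 genes open to naming moved by over 1.5 times, among them Mmp3 from 7.05 to 9.28, Plac8 from 8.37 to 9.71, Cox6a2 from -12.16 to -9.89 and Cdkn2a from 9.22 to 12.03 in log2 difference.

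Myl3, Cox6a2, cardiac troponin I (Tnni3) and the globin Hba-a2 were 8351-fold, 2089-fold, 2015-fold and 1742-fold lower, the tubulin Tubb3 301-fold higher and Steap1 at least 615-fold higher. Heart muscle genes fell in 26 of 28 cases and rose in 0 (0 higher and 26 lower when adjusted over the list alone, camera adjusted p = 3.29e-16, and adjusted p = 0.0933 with an estimated correlation). Mitochondrial genes fell with them, 29 of 29 of oxidative phosphorylation and 18 of 20 of fatty acid oxidation, and none rose. The first list had 0 higher and 29 lower when adjusted over the list alone (camera adjusted p = 3.29e-16, and adjusted p = 0.239 with an estimated correlation). The second had 0 higher and 18 lower when adjusted over the list alone (camera adjusted p = 2.80e-11, and adjusted p = 0.0903 with an estimated correlation). Endothelial genes fell in 17 of 20 cases and rose in 0 (0 higher and 18 lower when adjusted over the list alone, camera adjusted p = 2.66e-08, and adjusted p = 0.184 with an estimated correlation). Red cell genes fell in 5 of 5 with 0 higher (0 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.000449, and adjusted p = 0.239 with an estimated correlation). Cell cycle genes rose in 27 of 29 cases and fell in 0 (27 higher and 0 lower when adjusted over the list alone, camera adjusted p = 5.13e-11, and adjusted p = 0.304 with an estimated correlation). Fibroblast genes rose in 19 of 25 with 1 lower (19 higher and 1 lower when adjusted over the list alone, camera adjusted p = 4.70e-06, and adjusted p = 0.0933 with an estimated correlation). Matrix genes rose in 27 of 35 with 0 lower (28 higher and 1 lower when adjusted over the list alone, camera adjusted p = 1.24e-07, and adjusted p = 0.184 with an estimated correlation).

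Senescence and p53 genes were higher in 11 of 15 cases and lower in 1 (11 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.000147, and adjusted p = 0.108 with an estimated correlation). Cdkn2a was 1582-fold higher, measured on 1 of 2 ventricle arrays. Cytokine genes were higher in 13 of 17 cases and lower in 0 (13 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.000231, and adjusted p = 0.0933 with an estimated correlation). Lysosome genes were higher in 14 of 24 and lower in 1 (14 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.000918, and adjusted p = 0.239 with an estimated correlation). Epithelial and mesothelial genes fell in 8 of 13 cases and rose in 1 (1 higher and 8 lower when adjusted over the list alone, camera adjusted p = 0.00125, and adjusted p = 0.108 with an estimated correlation). Macrophage genes fell in 3 of 27 cases and rose in 0 (0 higher and 2 lower when adjusted over the list alone, camera adjusted p = 0.0134, and adjusted p = 0.644 with an estimated correlation). These were Ccr2, Cd163 and Lyve1. The size rested on single arrays, since the median of -1.70 became -0.11 without replicate 1 of the CD45-negative cells, where the list no longer passed (adjusted p = 0.784), and -3.54 without replicate 2. Regulators of the epithelial-mesenchymal transition rose (11 of 16 higher and 0 lower, 12 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.000390, and adjusted p = 0.304 with an estimated correlation), and so did immediate early genes (9 of 19 higher and 0 lower, 9 higher and 0 lower when adjusted over the list alone, camera adjusted p = 0.000517, and adjusted p = 0.239 with an estimated correlation). Fat cell genes fell (7 of 8 lower and 0 higher, 0 higher and 7 lower when adjusted over the list alone, camera adjusted p = 0.00131, and adjusted p = 0.239 with an estimated correlation). Mast cell genes (5 of 8 lower and 0 higher, 0 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.0123, and adjusted p = 0.436 with an estimated correlation), Schwann cell genes (5 of 9 lower and 0 higher, 0 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.0324, and adjusted p = 0.239 with an estimated correlation) and smooth muscle genes (8 of 15 lower and 2 higher, 2 higher and 8 lower when adjusted over the list alone, camera adjusted p = 0.0294, and adjusted p = 0.436 with an estimated correlation) fell as well. The Schwann cell list no longer passed without replicate 1 of the CD45-negative cells (adjusted p = 0.0901) or either ventricle replicate (0.0574 and 0.0571), nor the smooth muscle list without replicate 1 of the CD45-negative cells (0.0545) or replicate 2 of the ventricle (0.0960). Tissue, culture and RNA kit changed together between the cells and the ventricle, in this and the following comparisons with ventricle.

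CD45-positive cells were far richer in macrophage and chemokine transcripts than left ventricle. Gpnmb, a glycoprotein of lysosomes, was 2972-fold higher (log2 difference 11.54, SE 1.81, n = 2 per group), the lectin receptor Clec4d 534-fold higher, the protease Adam8 higher by a log2 difference of 9.96, and Arg1 at least 2700.5-fold higher. The cardiac myosin Myh6 was 12739-fold lower (log2 difference -13.64, SE 0.52, n = 2 per group) and its light chains Myl3 and Myl2 12535-fold and 11160.0-fold lower. Of 23074 genes tested with limma, 4226 were higher and 4576 lower in CD45-positive cells. With 1 array left out 31 of 166 genes open to naming moved by over 1.5 times, among them Gpnmb from 10.35 to 12.72, Rgs5 from -12.83 to -11.41 and Actc1 from -17.77 to -16.30 in log2 difference.

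The adhesion molecule Nrcam was 502-fold and the G-protein regulator Rgs1 at least 1046-fold higher, while the oxidase subunit Cox8b was 7418-fold lower and cardiac actin (Actc1) and Mb at least 42142-fold and 33973-fold lower. Macrophage genes rose in 22 of 29 cases and fell in 3 (24 higher and 4 lower when adjusted over the list alone, camera adjusted p = 0.000262, and adjusted p = 0.627 with an estimated correlation). Trem2 was 201-fold higher. The 3 that fell were Lyve1 (37.8-fold), Cd163 and Itgam, the last with a mean over all probes of 1.68 in the other direction. Lysosome genes rose in 22 of 25 cases and fell in 0 (22 higher and 0 lower when adjusted over the list alone, camera adjusted p = 5.86e-11, and adjusted p = 0.137 with an estimated correlation). Cytokine genes rose in 23 of 25 and fell in 0 (23 higher and 0 lower when adjusted over the list alone, camera adjusted p = 9.84e-09, and adjusted p = 0.183 with an estimated correlation). Cell cycle genes rose in 28 of 30 cases and fell in 0 (28 higher and 0 lower when adjusted over the list alone, camera adjusted p = 5.86e-11, and adjusted p = 0.400 with an estimated correlation).

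Heart muscle genes fell in 26 of 28 cases and rose in 0 (0 higher and 26 lower when adjusted over the list alone, camera adjusted p = 4.51e-16, and adjusted p = 0.137 with an estimated correlation). Oxidative phosphorylation genes fell in 29 of 29 with 0 higher (0 higher and 29 lower when adjusted over the list alone, camera adjusted p = 1.43e-15, and adjusted p = 0.274 with an estimated correlation). Endothelial genes fell in 18 of 20 with 0 higher (0 higher and 18 lower when adjusted over the list alone, camera adjusted p = 9.84e-09, and adjusted p = 0.211 with an estimated correlation). Mast cell genes fell in 7 of 8 cases and rose in 0 (0 higher and 7 lower when adjusted over the list alone, camera adjusted p = 0.0146, and adjusted p = 0.504 with an estimated correlation). Carboxypeptidase Cpa3 was at least 10.2-fold lower. Smooth muscle and pericyte genes fell in 9 of 15 cases and rose in 0 (0 higher and 9 lower when adjusted over the list alone, camera adjusted p = 0.00191, and adjusted p = 0.368 with an estimated correlation). Rgs5 was at least 1249.9-fold lower. Fatty acid oxidation genes (18 of 20 lower and 0 higher, 0 higher and 18 lower when adjusted over the list alone, camera adjusted p = 1.37e-10, and adjusted p = 0.106 with an estimated correlation) and red cell genes (4 of 5 lower and 0 higher, 0 higher and 4 lower when adjusted over the list alone, camera adjusted p = 0.00108, and adjusted p = 0.274 with an estimated correlation) fell. Senescence and p53 genes rose (9 of 15 higher and 1 lower, 10 higher and 1 lower when adjusted over the list alone, camera adjusted p = 8.66e-05, and adjusted p = 0.151 with an estimated correlation). Matrix genes (17 of 35 higher and 3 lower, 17 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.00532, and adjusted p = 0.400 with an estimated correlation), fibroblast genes (11 of 25 higher and 5 lower, 12 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.00894, and adjusted p = 0.234 with an estimated correlation) and regulators of the epithelial-mesenchymal transition (7 of 16 higher and 3 lower, 7 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.0473, and adjusted p = 0.611 with an estimated correlation) had more higher than lower genes among those passing. The fibroblast list no longer passed without either CD45-negative replicate, which share the fit (adjusted p = 0.0571 and 0.0573). These regulators no longer passed without either of them (0.0690 and 0.0692), replicate 1 of the ventricle (0.105) or replicate 2 of the CD45-positive cells (0.0780). Without replicate 2 of the CD45-positive cells the genes passing fell from 8802 to 5651.

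Passage-8 cells differed from left ventricle in heart muscle genes, as both primary groups did, and in Hox genes. The membrane protein Dlk1 was 940.3-fold higher (log2 difference 9.88, SE 0.29, n = 2 per group), Hoxa7 180.4-fold and Bnc1 170.1-fold higher, and Grem1, an inhibitor of bone morphogenetic proteins, at least 538-fold higher. Myh6 was 16288-fold lower (log2 difference -13.99, SE 0.52, n = 2 per group), and Actc1 and Mb were at least 52849-fold and 42605-fold lower. Of 23965 genes tested with limma, 4876 were higher and 4514 lower in passage-8 cells. With 1 array left out 41 of 156 genes open to naming moved by over 1.5 times, among them Thbs1 from 5.74 to 8.43 and Tcap from -13.43 to -12.20 in log2 difference.

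Thrombospondin Thbs1 was 136-fold and Steap1 at least 374-fold higher, and Myl3, titin-cap (Tcap) and Hba-a1 were 13061-fold, 7222-fold and 5806-fold lower. Heart muscle genes fell in 26 of 28 cases and rose in 0 (0 higher and 26 lower when adjusted over the list alone, camera adjusted p = 2.55e-16, and adjusted p = 0.143 with an estimated correlation). Hox genes rose in 15 of 20 cases and fell in 0 (15 higher and 0 lower when adjusted over the list alone). Their median log2 difference was 3.86, or 3.53 with genes at their bound (camera adjusted p = 6.89e-06, and adjusted p = 0.174 with an estimated correlation). Macrophage genes fell in 21 of 28 cases and rose in 0 (0 higher and 22 lower when adjusted over the list alone, camera adjusted p = 6.89e-06, and adjusted p = 0.409 with an estimated correlation). C1qc was at least 288-fold lower. Endothelial genes fell in 17 of 20 and rose in 0 (0 higher and 18 lower when adjusted over the list alone, camera adjusted p = 1.97e-10, and adjusted p = 0.232 with an estimated correlation). Cell cycle genes rose in 27 of 30 and fell in 0 (28 higher and 0 lower when adjusted over the list alone, camera adjusted p = 4.10e-12, and adjusted p = 0.289 with an estimated correlation). Matrix genes rose in 24 of 35 cases and fell in 2 (24 higher and 2 lower when adjusted over the list alone, camera adjusted p = 4.25e-05, and adjusted p = 0.275 with an estimated correlation). Tenascin C (Tnc) was at least 34.6-fold higher. Cytokine genes had more higher than lower members (10 of 17 higher and 3 lower, 11 higher and 3 lower when adjusted over the list alone, camera adjusted p = 0.0188, and adjusted p = 0.258 with an estimated correlation), but with no filter on dim probes the direction of this list turned, to a median of -0.17 from 3.29. Senescence and p53 genes (9 of 15 higher and 1 lower, 10 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.0128, and adjusted p = 0.275 with an estimated correlation) and immediate early genes (10 of 19 higher and 1 lower, 10 higher and 1 lower when adjusted over the list alone, camera adjusted p = 0.00407, and adjusted p = 0.289 with an estimated correlation) also had more higher than lower members.

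Mitochondrial genes of oxidative phosphorylation (29 of 29 lower and 0 higher, 0 higher and 29 lower when adjusted over the list alone, camera adjusted p = 3.22e-16, and adjusted p = 0.275 with an estimated correlation) and fatty acid oxidation (19 of 20 lower and 0 higher, 0 higher and 19 lower when adjusted over the list alone, camera adjusted p = 1.37e-11, and adjusted p = 0.0875 with an estimated correlation) fell in passage-8 cells against ventricle. Smooth muscle genes fell (10 of 15 lower and 1 higher, 1 higher and 10 lower when adjusted over the list alone, camera adjusted p = 0.000916, and adjusted p = 0.275 with an estimated correlation), and so did Schwann cell genes (7 of 10 lower and 0 higher, 0 higher and 7 lower when adjusted over the list alone, camera adjusted p = 0.000886, and adjusted p = 0.258 with an estimated correlation). Genes of antigen presentation (9 of 15 lower and 0 higher, 0 higher and 9 lower when adjusted over the list alone, camera adjusted p = 0.00138, and adjusted p = 0.302 with an estimated correlation) and of T, B and NK cells (4 of 9 lower and 0 higher, 0 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.0442, and adjusted p = 0.407 with an estimated correlation) were lower. Red cell genes (5 of 6 lower and 0 higher, 1 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.00407, and adjusted p = 0.289 with an estimated correlation), mast cell genes (5 of 8 lower and 0 higher, 0 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.0122, and adjusted p = 0.373 with an estimated correlation) and fat cell genes (5 of 8 lower and 0 higher, 0 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.0105, and adjusted p = 0.301 with an estimated correlation) fell too. The T, B and NK cell list no longer passed without replicate 1 of the ventricle (adjusted p = 0.133) or of the passage-8 cells (0.135), nor the senescence list without replicate 1 of the ventricle (0.0557). The cytokine list no longer passed without either CD45-negative replicate (adjusted p = 0.0586 and 0.0587). Over the 3 comparisons with ventricle, 1943 of 22077 genes were higher in all 3 cell groups and 2677 lower in all 3.

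**Figure D3:**
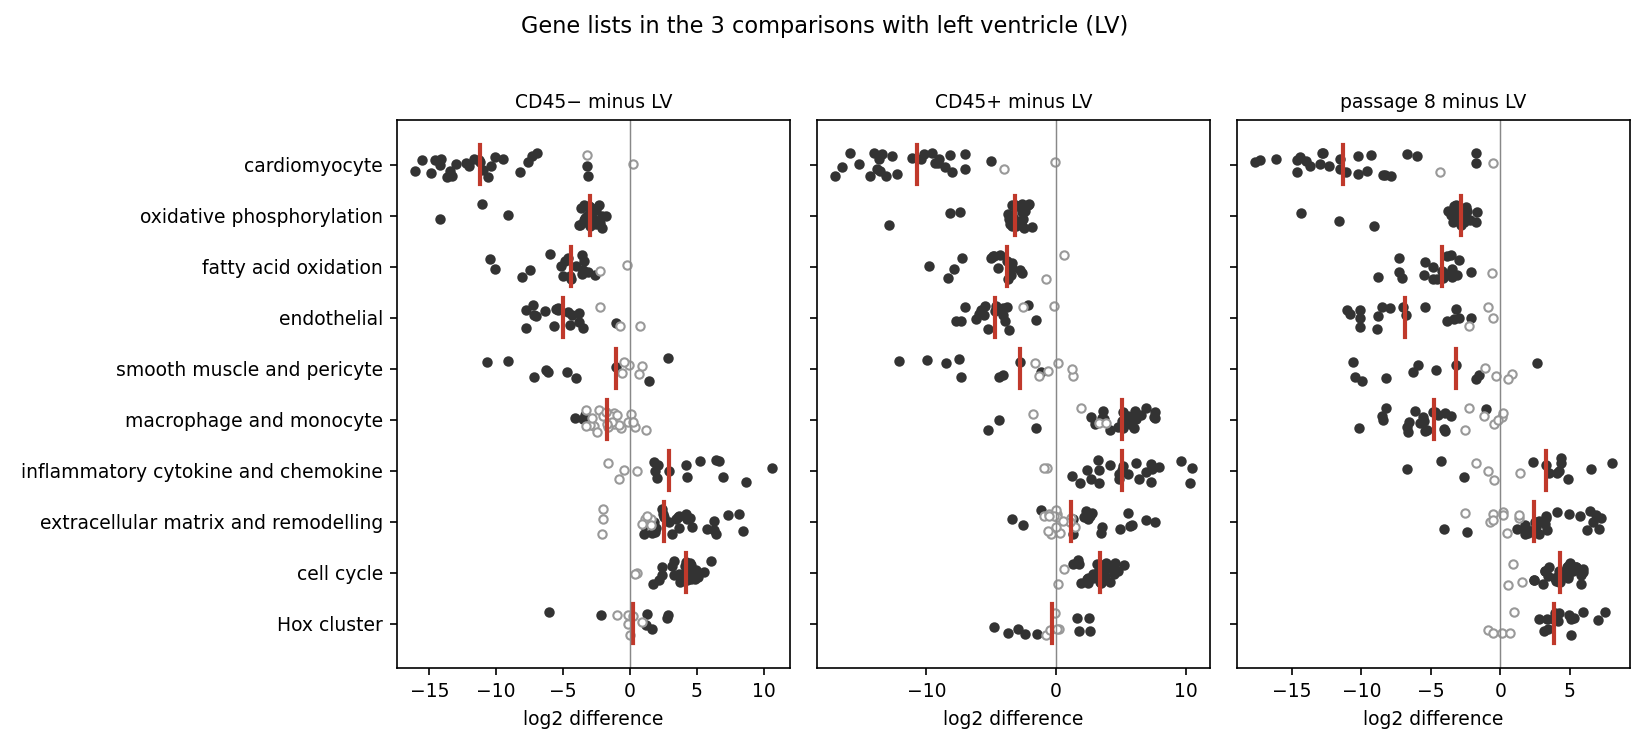
Log2 differences from left ventricle of the tested members of 10 gene lists in the 3 cell groups, with 1 point per gene, filled where the gene passed the limma test, and a vertical bar at the median of each list. Heart muscle genes lie at medians of -11.24, -10.77 and -11.33, cell cycle genes at 4.16, 3.36 and 4.25, and macrophage genes above 0 in CD45-positive cells only, at a median of 5.10 against -1.70 and -4.80. With 1 array left out the heart muscle medians ran from -11.50 to -10.93, -11.27 to -10.74 and -12.36 to -10.17, in the same order. The cell cycle medians then ran from 3.57 to 4.83, 2.84 to 3.80 and 3.85 to 4.71.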

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

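The counts of shared genes with 1 array left out were chosen only after the result was seen. The direction and threshold side of 276 of 835 gene results and 40 of 171 list results stayed the same under every alternative. Over all alternatives, 14992 of 16700 gene values stayed the same, 1665 were weaker, 22 stronger and 21 reversed, and for lists 3424 of 3729 stayed the same, 192 were weaker, 108 stronger and 5 reversed. Sign changes where neither value passed count as the same, 121 in all (5 for genes and 116 for lists). Of 277 counts, 245 stayed within 1.5 times. Signal over background limits dim genes, and the lone array left in a group is assumed to vary like the other groups.

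At an adjusted p under 0.01 the genes passing in CD45-negative against CD45-positive cells, passage-8 against CD45-positive cells and passage-8 against CD45-negative cells fell from 4677, 5509 and 3173 to 1919, 2810 and 971, by construction. With only the 4 arrays compared, the first came to 1973 and the last to 181. Array weights gave 2094 for the last. The 4-array fit had fewer arrays in every comparison, yet 10 counts stayed within the limit set for counts and only these 2 moved. Both involve CD45-negative cells, whose replicates had a standard deviation of 0.755 log2 units, against 0.247 in CD45-positive and 0.206 in passage-8 cells. CD45-negative cells against ventricle was among those that stayed. The main fit pools the spreads of all 4 groups, and that of CD45-negative cells is the widest. Over genes as a whole the pooled spread therefore understates the error of CD45-negative cells. By how much it does so for single genes was not tested. Leaving out 1 array gave 802 to 5988, 2182 to 6310, and 851 to 5175, and in the comparisons of CD45-negative, CD45-positive and passage-8 cells with ventricle 7625 to 9798, 5651 to 9384 and 7088 to 10002. The shared genes ranged from 503 to 3177 in place of 2587, and the lists passing in passage-8 against CD45-negative cells from 7 to 14. Under normexp background correction 31.4% of the genes passing in passage-8 against CD45-negative cells were higher, against 49.95%, and the median difference of all genes was 0.32 in CD45-negative against CD45-positive cells. Except where stated, here and below, the cause was not tested.

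With genes well above background on all 8 arrays only, fewer genes were tested and lists passing came to 6, 7 and 2 in the comparisons among cells, in the order above, and to 9 in passage-8 cells against ventricle. In passage-8 against CD45-negative cells the mesothelial median was then 4.29 (adjusted p = 0.0748) and the Hox median 1.74 (adjusted p = 0.184). With an estimated correlation 0 lists passed in all 6 comparisons, with unchanged medians of -6.56 (p = 0.587) for macrophage and 1.33 (p = 0.110) for fibroblast genes between the primary groups, -9.23 (p = 0.381) for macrophage and 4.07 (p = 0.127) for Hox genes in passage-8 against CD45-positive cells, 5.04 (p = 0.0776) for mesothelial and 3.85 (p = 0.0776) for Hox genes against CD45-negative cells, and -11.24 (p = 0.0933), -10.77 (p = 0.137) and -11.33 (p = 0.143) for heart muscle genes against ventricle.

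Values that reversed under normexp were, in CD45-negative against CD45-positive cells, Il1rl1 0.33, Cd2 0.21, Kcna1 0.39, Hoxb7 0.19, Hoxb6 0.57 and the oxidative phosphorylation list -0.12, in passage-8 against CD45-negative cells Ppargc1a -0.28, and against ventricle Cd3d 0.056, Slamf1 0.18, Hoxb3 -1.59 and Hoxd4 0.11 in CD45-negative and Hoxb3 -2.66 in CD45-positive cells. The authors' table gave Hoxb3 -2.79 and -3.11 there. The mean over probes gave Itgam -1.52 and Il1rl1 0.48 between the primary groups, Flt3 -0.22 and Hoxb3 -0.58 in CD45-negative cells against ventricle, and Itgam 1.68, Nkg7 -0.23 and Hoxb3 -1.64 in CD45-positive cells against ventricle. Lists that reversed were the inflammatory list in passage-8 cells against ventricle with no filter (-0.17), the endothelial list in passage-8 against CD45-positive cells on genes above background on all arrays (0.14), and the glycolysis list in CD45-positive cells against ventricle with each probe on its own (-0.15). Leaving out 1 array, the neutrophil list in passage-8 against CD45-negative cells ran from -1.62 to 0.15 and Kit in CD45-negative against CD45-positive cells from -2.89 to 1.90.

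With the replicate number as a block the 6 counts were 4350, 5191, 2672, 8713, 8625 and 9238, all within 1.5 times, and replicate differences correlated between groups by -0.197 to 0.193, over 0.1 in 2 of 6 pairs of groups. Replicate 1 arrays lie in row 1 and replicate 2 arrays in row 2 of the slide, and the labels name no shared animal or batch, so the numbers were not used to pair samples.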

Other observations

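Of the tests below, those of the whole-array rise, of changed copy number and of a few strongly changed genes were set before their results were seen, and the tests of the shared RNA pool, of Timd4 and Lyve1, of chance, of outgrowth and of another source only after their results had been seen.

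Energy and stress genes set all 3 cell groups apart from ventricle. Glycolysis genes rose in 7 of 16 cases in CD45-negative cells, 6 of 16 in CD45-positive cells and 7 of 16 in passage-8 cells, and none fell. In CD45-negative cells the count was 7 higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.0134, and adjusted p = 0.239 with an estimated correlation). In CD45-positive cells it was 6 higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.0146, and adjusted p = 0.274 with an estimated correlation), and in passage-8 cells 7 higher and 0 lower when adjusted over the list alone (camera adjusted p = 0.00624, and adjusted p = 0.275 with an estimated correlation). With each probe on its own the direction of this list turned in CD45-positive cells, to a median of -0.15. The lactate exporter Slc16a3 was 129-fold, 64.3-fold and 71.1-fold higher. In CD45-negative cells the glycolysis list no longer passed without replicate 1 of these cells (adjusted p = 0.0914). Immediate early genes rose in 12 of 19 cases in CD45-positive cells and fell in 0 (13 higher and 0 lower when adjusted over the list alone, camera adjusted p = 2.49e-05, and adjusted p = 0.243 with an estimated correlation), with Fos 73.3-fold higher. Between the primary groups this list did not pass (median log2 difference -0.18), while its member Atf3 was 64.5-fold lower in CD45-negative cells.

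Genes of blood cell precursors moved singly. The transcription factor Runx1 was 31.6-fold, 36.3-fold and 58.7-fold higher than in ventricle in CD45-negative, CD45-positive and passage-8 cells, while Lmo2, a partner of Tal1, was at least 1619.8-fold lower in passage-8 than in CD45-positive cells. The list as a whole passed in none of the 6 comparisons, and nor did the pluripotency list. Interferon response genes went both ways between the primary groups, 7 higher and 5 lower of 30 in CD45-negative cells (7 higher and 5 lower when adjusted over the list alone, camera adjusted p = 0.894), with Mx2 4.27-fold higher.

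Macrophage genes were brighter on replicate 2 than on replicate 1 of the CD45-negative cells, although the sort gate excluded CD45, with 26 and 22 of 28 members of the list above background. Over 311 genes at least 64-fold higher in CD45-positive than in passage-8 cells, the median on replicate 2 was 4.41% of the CD45-positive level, against 0.578% on replicate 1, and the interquartile range on replicate 2 was 1.498 log2 units, under the 2 set for RNA of such cells mixed in at 1 share. Timd4 and Lyve1 were picked because they stood out. They lay above their CD45-positive level by 3.568 log2 units or more, which that explanation cannot give for these 2 genes. Cd163 was not well above background on replicate 2 or in CD45-positive cells, so it cannot be compared. Of the 28 list members, which exclude Timd4, only Lyve1 and Itgam lay above the CD45-positive level, on both replicates. So did 7 of the 311 genes on replicate 2. For Itgam the mean over all probes went the other way between the primary groups (log2 difference -1.52). A rise of dim signal over the whole array would also have raised 313 ventricle-specific genes. They rose by 0.2454 times as much as the 311 genes (by 0.74 log2 units), under the 0.5 set for such a rise as the whole cause. The 19018 genes above background on both CD45-negative arrays moved by a median of -0.06, a value that leaves out genes dim on either array. On the replicate 2 array alone 218 genes stood above background, against 1 to 8 on the others, so this array stands apart in other genes too. Carry-over during sorting, low expression within the sorted cells and, for Timd4 and Lyve1, other macrophages stay open.

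Whole chromosomes shifted in passage-8 cells, relative to the median of all genes well above background on all 8 arrays, which was subtracted. Against CD45-negative cells, CD45-positive cells and ventricle the medians were 0.40, 0.36 and 0.37 log2 units for chromosome 19 and -0.38, -0.32 and -0.26 for chromosome 4. In each of these comparisons at least 4 chromosomes lay outside all 10000 random gene sets, where chance spread would leave at most 1 outside. Each of the 4 most shifted chromosomes was cut into 4 segments of equal gene number. Under changed copy number all would move with their chromosome in each of these comparisons. Of these 48 values 47 did, which the rule set for it leaves open. The comparisons share the passage-8 arrays, so the 48 values are not independent. For a few strongly changed genes, the rule set beforehand asked whether genes differing by under 1 log2 unit kept less than 0.5 of the shift. They kept 0.1773 to 0.8212, with 6 of 12 shares under 0.5 and none of them against CD45-negative cells. The filter is on the change itself, so even an equal shift of every gene would be kept only in part. Against ventricle an even shift would keep 0.4627 to 0.4813, so the rule cannot decide there. Against CD45-negative cells it would keep 0.7273 to 0.7598, and the shares were 0.6415 to 0.8212. Against CD45-positive cells it would keep 0.6476 to 0.7031, and the shares were 0.2758 to 0.6295, so these comparisons differ. Copy number and strongly changed genes both stay open, and by values chosen after that result was seen 11 of 12 shares lay below that of an even shift and 57.42% to 71.28% of genes lay on the side of their chromosome's shift.

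Mesothelial and Hox genes rose together in passage-8 cells, which outgrowth of mesothelial cells from the CD45-positive culture, a change within the cells, or another source of cells might each give. Outgrowth with an unchanged profile would raise genes that only mesothelial cells express by 1 factor, and the log2 differences of the mixed epithelial and mesothelial list from CD45-positive cells ranged over 7.079 units, from -1.15 for Krt5, an epithelial keratin, to 5.93 for Bnc1, with Upk1b the lowest other member at 0.18, which cannot decide, since other cells of that culture may express the genes that rose less. For the Hox genes the test cannot decide, because their median exceeded that of the mesothelial list by 1.619 log2 units with genes at their lower bound and by 2.296 without bounds, on either side of the limit of 1.974, which is a spread of single genes and wide for a median. Among sex-linked genes Eif2s3y (log2 difference -2.33), Ddx3y (-2.80) and, measured on 1 of 2 passage-8 arrays, Xist (-6.65) were lower, Uty (-1.84, adjusted p = 0.165) did not pass and Kdm5d was above background on no array. Outgrowth stays open for both lists, and another source of cells and changes of these genes in culture cannot be told apart, since the sex of the donors is not given.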
